A study of Mus musculus with 24 samples.

How the data were processed

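Total RNA of dorsal root ganglia, intact or after 4 days in culture, was sequenced from 12 C57BL/6 mice, with 1 intact and 1 cultured library per mouse. Per the labels, stranded single-end libraries of total RNA from both laboratories were prepared in one laboratory and sequenced in one run. The authors deposited a table of TPM values (transcripts, scaled to a fixed total per library) for all coding genes, rounded to 1 decimal, in which each library sums to about the same total. Their notes name the aligner STAR and the genome build GRCm38.p5, but not the counting tool, the annotation release or any scaling between libraries. The table holds no read counts, so counting intervals and the limit set by a count of 0 could not be computed, and a listed 0 is less than the table's rounding step or a failed estimate. Uniquely mapped reads per library, as listed in the table, are given with the data. The authors' deposited table also marks the genes that its authors took to differ between cultured and intact ganglia. The criteria were not stated, and that mark was used only to count shared genes.

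The table held 21962 entries. Where a symbol occurred more than once, the entry with the highest mean TPM was kept, so 29 duplicates were dropped and 21933 genes were left. Genes with at least 1 TPM in at least 6 of the 24 libraries were tested (14459), and 7474 were listed but not tested. Values were analysed as log2(TPM + 1). All 24 libraries could be assigned to a group, and none was left out.

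Linear models were fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend) in R 4.3.3, with a mean for each of the 4 groups of 6 libraries and 20 residual degrees of freedom. P values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. The comparisons were cultured against intact ganglia in each laboratory, the difference of these effects, and Price against Gereau in intact ganglia and in cultures. Sex was tested with a mean for each of the 8 combinations of group and labelled sex (16 residual degrees of freedom), averaging over laboratories. The fold change of a gene near 1 TPM is understated on this scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

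Libraries of the same mouse are tied by the mouse number in the table. After group means were removed, the correlation across genes of the intact and cultured library of the same mouse averaged 0.0277 in Price and 0.0230 in Gereau, against −0.0055 and −0.0043 for libraries of different mice, and 2 of 6 intact libraries in each laboratory correlated best with the cultured library of the same mouse. The model therefore had no mouse term, and the fit with a block for each mouse (10 residual degrees of freedom) was an alternative for the culture effects. Comparisons of laboratories, and of labelled sexes within intact ganglia or cultures, used a fitted correlation between libraries of a mouse instead.

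The 35 gene lists named in the report were fixed before the data were examined. The 34 lists with at least 5 tested members were tested with camera on the same model with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list. P values were adjusted over the lists of a comparison. Each of 10 neuronal lists was also compared with the pan-neuronal list by subtracting the mean log2 values within each library and comparing 6 cultured with 6 intact libraries of a laboratory in a two-sided exact permutation test, adjusted over 20 tests.

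The genes named were chosen by a rule also fixed before the data were examined. For each comparison of culture and laboratory the rule takes the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean of at least 10 TPM in the higher group and no overlap between groups. For the difference of culture effects it takes 6 in each direction with no rule on overlap, and for each sex comparison up to 6 called genes in each direction. Symbols made of Gm and a number, ending in Rik, or starting with mt-, Rn or Snor were left out. From each gene list it takes up to 4 called members with the largest absolute log2 fold change, or the member with the highest mean where none was called. A further 22 genes are always reported, and the text names the part of these that each comparison needs. Genes named outside the rule are given as chosen after their values were seen.

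The alternatives fixed beforehand were a pseudocount of 0.1 TPM, a minimum of 5 TPM, no filter, quantile and upper-quartile normalization, array weights, no mean-variance trend, a fit to the libraries of the comparison alone, sex as a covariate, the block for each mouse (called the replicate block), leaving out each of the 24 libraries, the adjusted p as the only criterion, camera with an estimated correlation, and a sign-flip test over mice. Those added after the data were seen were leaving out genes that were intermittently listed near 0, fitting sex within each laboratory, and leaving out both libraries in doubt. The steps were also tested on simulated data of the same size. Of 14459 genes at most 3 unchanged ones were called, and of 50 changed genes 18 to 24 were recovered at a log2 change of 1, 47 to 50 at 1.5, 46 to 49 at 2 and 50 at 3. Camera passed 50 of 50 shifted and 0 of 50 unshifted lists, and the permutation test passed 22 of 400 unshifted and 100 of 100 shifted lists. Simulated genes were drawn independently, so the camera counts do not test lists of correlated genes. The estimated correlation of the pan-neuronal list, for example, was 0.555.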

Results

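Gene expression was measured by RNA sequencing of total RNA from mouse dorsal root ganglia, the clusters of sensory neurons beside the spinal cord that also hold glia, connective tissue, vessels and immune cells. The 24 libraries came from 12 C57BL/6 mice and fell into 4 groups of 6: intact ganglia and dissociated cultures from each of 2 laboratories, named Price and Gereau in the labels. Each mouse gave 1 intact and 1 cultured library, and each group held 3 libraries labelled male and 3 labelled female. Cultures were kept for 4 days. The Price medium contained serum, nerve growth factor at 5 ng/ml, and 5-fluorouridine at 3 µg/ml with uridine at 7 µg/ml, nucleosides used to hold back dividing cells. The Gereau protocol is cut short in the labels. Each laboratory used its own protocol, so laboratory and culture protocol cannot be told apart. The labels give conflicting ages for the Price mice and, as cut short, none for the Gereau mice, so age was not used and may differ between the laboratories.

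The uniquely mapped reads per library, as listed in the deposited table, ranged from 11760256 to 13173528 in Price intact ganglia and from 11025628 to 13433467 in Price cultures. They ranged from 14957918 to 18174167 in Gereau intact ganglia and from 10464363 to 18645619 in Gereau cultures, where replicate 4 had the fewest. Between 12851 and 13828 genes reached 1 TPM in a library. Pearson correlations between libraries of a group, computed across genes that are not independent replicates, lay between 0.971 and 0.986 in 3 groups and between 0.941 and 0.986 in Gereau cultures. The median SD of a gene's log2 value was 0.175 in Price intact ganglia, 0.180 in Price cultures, 0.147 in Gereau intact ganglia and 0.302 in Gereau cultures. The last value was 0.191 without replicate 4.

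**Figure D1:**
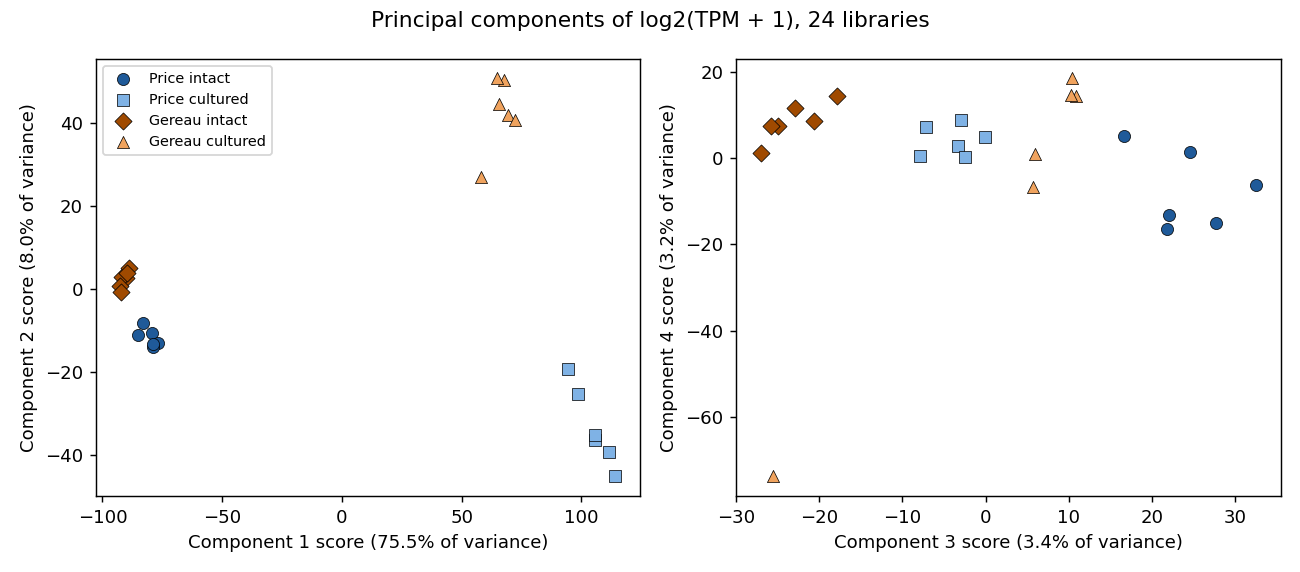
Principal components 1 and 2 of log2(TPM + 1) for the 24 libraries, 1 point per library, coloured by group; the axis labels give the percent of variance. Intact and cultured libraries separate on component 1, which carried 75.5% of the variance, and component 2 carried 8.04%.

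The first question was which genes, and in particular which receptors and channels that drugs act on, differ between cultured and intact ganglia, and it was asked in each laboratory separately. In both laboratories, cultures had lower transcript levels of neuronal, myelin and haemoglobin genes than intact ganglia and higher levels of cell cycle, matrix and cytokine genes. Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131.11, chromosome X, plus strand, 20870166 to 20874735 on GRCm38), rose from 5.43 ± 1.15 to 3204 ± 129.6 TPM in Price (mean ± SD, n = 6 libraries per group here and below) and from 4.32 ± 2.32 to 1987 ± 543 TPM in Gereau. Serpine1, the inhibitor of plasminogen activators (ENSMUSG00000037411.10, chromosome 5, minus strand, 137061504 to 137072268), rose from 1.48 ± 0.50 to 1355 ± 239 TPM in Price and from 0.40 ± 0.25 to 279 ± 90.8 TPM in Gereau. Mpz, the major protein of peripheral myelin (ENSMUSG00000056569.10, chromosome 1, plus strand, 171150711 to 171161130), fell from 24126 ± 3913 to 227 ± 16.7 TPM in Price and from 3004 ± 546 to 196 ± 27.2 TPM in Gereau.

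Of 14459 genes tested with limma on log2(TPM + 1), 5869 were called in Price cultures (2685 higher and 3184 lower) and 5139 in Gereau cultures (2585 higher and 2554 lower), a call being an adjusted p under 0.05 with an absolute log2 fold change of at least 1. The median log2 fold change of all tested genes was 0.01 in Price and 0.02 in Gereau. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes near 1 TPM. All values are relative to a library's total, so a gene's TPM also moves with the other genes of the library.

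Of 34 gene lists tested with camera, 27 shifted in Price (9 up and 18 down) and 27 in Gereau (12 up and 15 down). Each camera test assumed a correlation of 0.01 between the genes of a list. With a correlation estimated from the data, 3 lists still passed in each laboratory: the cell cycle and cytokine lists in both, p53 targets in Price, and matrix proteases in Gereau. Counts of list members called when p values were adjusted over the list alone were identical to those adjusted over all genes for every list in both culture comparisons.

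**Figure D2:**
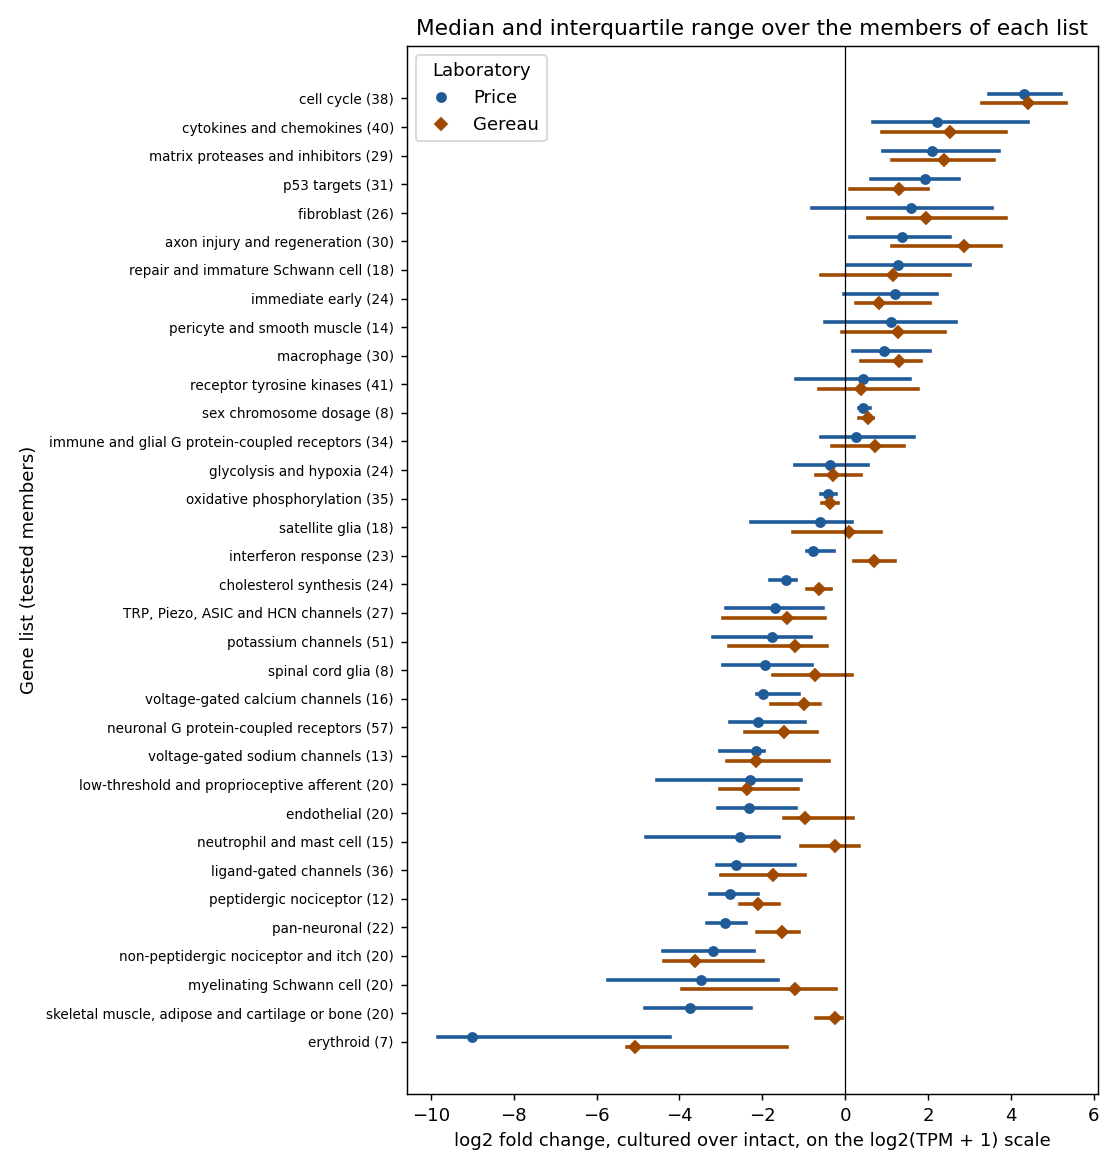
Median log2 fold change of each gene list in the culture comparisons of both laboratories, on a log2 scale, with the quartiles of its members as bars. Lists of neuronal subtype markers, pan-neuronal markers and myelin genes lie below 0, axon injury genes lie above it, and the cell cycle list lies highest, at 4.32 in Price and 4.42 in Gereau.

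Genes of sensory neurons fell in culture. Of 22 pan-neuronal markers, 21 fell in Price (median log2 fold change −2.90, adjusted p = 2.83e-08) and 17 in Gereau (−1.51, adjusted p = 3.88e-06). Snap25, a protein of synaptic vesicle fusion, fell from 989 ± 153 to 47.7 ± 18.4 TPM in Price and from 1378 ± 115 to 171 ± 46.7 TPM in Gereau. Among 12 markers of peptidergic nociceptors, 11 fell in Price (median −2.77, adjusted p = 5.6e-05), and 10 fell and 1 rose in Gereau (−2.12, adjusted p = 0.000294). Calca, which encodes the neuropeptide CGRP (ENSMUSG00000030669.13, chromosome 7, minus strand, 114631478 to 114636357), fell from 3167 ± 349 to 736 ± 305 TPM in Price and from 3978 ± 334 to 979 ± 46.8 TPM in Gereau. Tac1, the precursor of substance P, had log2 fold changes of −3.70 and −4.47. The gene that rose in Gereau was Adcyap1, the precursor of the neuropeptide PACAP, named after its values were seen.

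Of 20 markers of non-peptidergic nociceptors and itch neurons, 17 fell and 1 rose in Price (median −3.20, adjusted p = 2.97e-07), and 15 fell and 1 rose in Gereau (−3.63, adjusted p = 3.29e-07). Mrgprd, an itch and pain receptor (ENSMUSG00000051207.7, chromosome 7, plus strand, 145314835 to 145324086), was listed at 43.9 to 77.5 TPM in Price intact libraries and at 73.2 to 101.9 TPM in Gereau intact libraries. In Price cultures it was listed at 0 in 5 of 6 libraries and reached at most 0.2 TPM, and in Gereau cultures it was listed at 0 in 4 and reached at most 0.1 TPM. P2rx3, an ATP-gated channel of the same neurons, fell from 125 ± 16.1 to 55.8 ± 25.2 TPM in Price but was not called in Gereau, where it was at 164 ± 26.4 and 237 ± 57.3 TPM. Of 20 markers of low-threshold and proprioceptive afferents, 15 fell and 1 rose in Price (median −2.30, adjusted p = 1.17e-05) and 16 fell and 1 rose in Gereau (−2.36, adjusted p = 2.8e-06). Th, tyrosine hydroxylase, was listed at 119 to 197.3 TPM in intact and at most 4 TPM in cultured Price libraries, and fell from 217 ± 21.7 to 10.03 ± 2.53 TPM in Gereau. The 4 neuronal marker lists gave adjusted p = 0.101 to 0.184 in Price and adjusted p = 0.131 to 0.269 in Gereau with an estimated correlation.

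Channels and neuronal receptors mostly fell. Of 13 voltage-gated sodium channel genes, 11 fell in Price (median −2.15, adjusted p = 2.45e-05) and 7 in Gereau (−2.15, adjusted p = 0.000249). Scn10a, which encodes Nav1.8, fell from 183 ± 39.3 to 26.5 ± 11.2 TPM in Price and from 249 ± 75.3 to 34.1 ± 10.3 TPM in Gereau. Scn9a, which encodes Nav1.7, fell from 25.9 ± 15.3 to 5.50 ± 2.57 TPM in Price and was not called in Gereau (log2 fold change −0.18, adjusted p = 0.655). In Gereau intact ganglia Scn9a was at 54.8 TPM in replicate 1 and at 16.6 to 18.3 TPM in the other libraries, which raises the mean of that group. Of 16 voltage-gated calcium channel genes, 12 fell in Price (median −1.98, adjusted p = 0.000174) and 8 in Gereau (−0.99, adjusted p = 0.00193), among them Cacna2d2, a subunit bound by gabapentinoids, with log2 fold changes of −2.42 and −2.62. Cacna2d1, a related subunit on the same list, was not called in either laboratory (−0.35 in Price and 0.85 in Gereau). Of 51 potassium channel genes, 37 fell and 2 rose in Price (median −1.77, adjusted p = 2.93e-09), and 30 fell and 2 rose in Gereau (−1.20, adjusted p = 2.57e-08). The sodium, calcium and potassium channel lists gave adjusted p = 0.101 to 0.128 in Price and adjusted p = 0.147 to 0.2 in Gereau with an estimated correlation.

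Among 27 TRP, Piezo, ASIC and HCN channel genes, 18 fell and 2 rose in Price (median −1.70, adjusted p = 0.000343), and 15 fell and 1 rose in Gereau (−1.41, adjusted p = 0.000149). Trpv1, the capsaicin receptor, fell from 97.0 ± 14.7 to 28.1 ± 12.4 TPM in Price and from 133 ± 8.80 to 31.7 ± 5.83 TPM in Gereau. Of 36 ligand-gated channel genes, 28 fell and 2 rose in Price (median −2.64, adjusted p = 3.46e-08), and 27 fell and 4 rose in Gereau (−1.73, adjusted p = 1.8e-07). Htr3a, a serotonin-gated channel, fell from 159 ± 17.3 to 4.27 ± 2.18 TPM in Price and from 209 ± 18.1 to 8.68 ± 1.46 TPM in Gereau. Of 57 neuronal G protein-coupled receptor genes, 42 fell and 1 rose in Price (median −2.10, adjusted p = 7.71e-12), and 38 fell and 2 rose in Gereau (−1.47, adjusted p = 3.86e-09). Oprm1, the µ-opioid receptor, was listed at no more than 2.1 TPM in any library and was not called in either laboratory. With an estimated correlation the last 3 lists gave adjusted p = 0.101 to 0.167 in Price and adjusted p = 0.165 to 0.195 in Gereau.

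Among 34 immune and glial G protein-coupled receptor genes, 13 rose and 6 fell in Price, where the list did not shift (adjusted p = 0.2), and 13 rose and 5 fell in Gereau (median 0.72, adjusted p = 0.0498). The Gereau call ended with an estimated correlation (adjusted p = 0.473) and without the 2 libraries in doubt, Gereau cultured replicate 4 and Price intact replicate 4 (adjusted p = 0.064), against 0.0241 to 0.0467 under the other alternatives. C3ar1, a complement receptor, rose in both, with log2 fold changes of 2.26 and 2.40. Of 41 receptor tyrosine kinase genes, 15 rose and 12 fell in Price, and 17 rose and 8 fell in Gereau, with no shift of the list (adjusted p = 0.383 and 0.168). Axl, a receptor used in clearing dead cells, rose from 31.9 ± 5.14 to 642 ± 60.5 TPM in Price and from 26.1 ± 3.16 to 422 ± 103 TPM in Gereau. Ntrk1, the receptor of nerve growth factor, fell from 271 ± 22.1 to 32.4 ± 15.5 TPM in Price, and its log2 fold change in Gereau was −2.48.

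Genes induced in sensory neurons by axon injury rose in both laboratories: 16 of 30 in Price, where 3 fell (median 1.37, adjusted p = 0.00284, and adjusted p = 0.33 with an estimated correlation), and 22 of 30 in Gereau, where 1 fell (2.86, adjusted p = 2.78e-08, and adjusted p = 0.149 with an estimated correlation). Atf3, a transcription factor induced by nerve injury (chromosome 1, minus strand, 191170296 to 191218039), rose from 11.3 ± 2.21 to 255 ± 75.6 TPM in Price. In Gereau it rose to 733 ± 61.5 TPM, from 61.1 TPM in intact replicate 3 and 8.6 to 15.7 TPM in the other 5 intact libraries. Gal, the neuropeptide galanin (ENSMUSG00000024907.6, chromosome 19, minus strand, 3409919 to 3414472), rose in Gereau from 80.7 ± 16.2 to 736 ± 163 TPM and was not called in Price (60.2 ± 18.7 and 62.9 ± 25.7 TPM). Gap43, a growth cone protein, and Hspb1, a heat shock protein, fell in Price (log2 fold changes −1.54 and −1.44), and Nppb, a peptide of itch neurons, fell in both (−2.59 and −2.92). These last 3 genes were chosen after their values were seen.

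Of 20 genes of myelinating Schwann cells, 16 fell and 1 rose in Price (median −3.48, adjusted p = 3.14e-07, and adjusted p = 0.101 with an estimated correlation). In Gereau, 11 fell and 2 rose (−1.21, adjusted p = 0.00183, and adjusted p = 0.277 with an estimated correlation). Prx, the myelin protein periaxin, fell from 997 ± 178 to 10.4 ± 2.66 TPM in Price and from 198 ± 29.8 to 11.6 ± 1.48 TPM in Gereau. Of 18 genes of repair and immature Schwann cells, 11 rose and 2 fell in Price (median 1.26, adjusted p = 0.00462, and adjusted p = 0.223 with an estimated correlation). In Gereau, 10 rose and 3 fell (1.15, adjusted p = 0.0301, and adjusted p = 0.391 with an estimated correlation). Gdnf and Artn, growth factors of the GDNF family, had log2 fold changes of 5.36 and 5.12 in Price and of 3.90 and 4.79 in Gereau. The 18 satellite glia genes did not shift (adjusted p = 0.108 in Price and 0.584 in Gereau), with 2 rising and 7 falling in Price and 4 rising and 6 falling in Gereau. Fabp7, a lipid-binding protein of satellite glia, was not called in either laboratory (627 ± 63.7 and 688 ± 102 TPM in Price). Apoe fell in both (−3.65 and −2.24).

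Of 30 macrophage genes, 14 rose and 5 fell in Price (median 0.94, adjusted p = 0.0334), and 18 rose and 4 fell in Gereau (1.30, adjusted p = 0.0107). With an estimated correlation both calls ended (adjusted p = 0.593 and 0.526), and the Price call also ended without the 2 libraries in doubt (adjusted p = 0.0727, against 0.0119 to 0.0295 under the other alternatives). Cd68, a lysosomal protein of phagocytes, rose from 7.85 ± 1.09 to 54.8 ± 10.9 TPM in Price and from 5.32 ± 0.47 to 72.0 ± 19.2 TPM in Gereau. Other members of the list fell in both, among them Cd74 (log2 fold changes −4.59 and −4.32) and H2-Aa (−4.82 and −5.08), which act in MHC class II antigen presentation, and Aif1, a general macrophage marker, was not called. The list of T, B and NK cell genes had 3 tested members and no list test. All 3 fell in Price, and Cd79a and Lck fell in Gereau (−1.54 and −1.01), the Lck call ending without Gereau intact replicate 5 (−0.90) among other libraries left out, and in both laboratories after quantile normalization (−0.78 in Price).

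Of 15 neutrophil and mast cell genes, 13 fell in Price (median −2.53, adjusted p = 0.000343, and adjusted p = 0.167 with an estimated correlation), where Camp, an antimicrobial peptide of neutrophils, had a log2 fold change of −5.24. In Gereau the list did not shift (4 lower and 1 higher, adjusted p = 0.442). Of 20 endothelial genes, 15 fell and 1 rose in Price (median −2.32, adjusted p = 7.15e-05, and adjusted p = 0.138 with an estimated correlation). In Gereau, 9 fell and 1 rose (−0.96, adjusted p = 0.0416, and adjusted p = 0.434 with an estimated correlation). The Gereau endothelial call also ended with a pseudocount of 0.1 TPM (adjusted p = 0.0549, against 0.0388 to 0.042 under the other alternatives). Cldn5, a tight junction protein, fell from 65.1 ± 7.49 to 0.38 ± 0.20 TPM in Price and from 33.3 ± 9.29 to 3.23 ± 1.57 TPM in Gereau. Of 14 pericyte and smooth muscle genes, 7 rose and 3 fell in Price with no shift of the list (adjusted p = 0.108), and 9 rose and 2 fell in Gereau (median 1.28, adjusted p = 0.0296, and adjusted p = 0.195 with an estimated correlation). Acta2, smooth muscle actin, rose from 41.3 ± 12.2 to 1607 ± 166 TPM in Price and from 15.2 ± 2.21 to 717 ± 229 TPM in Gereau. Rgs5, on the same list, went the other way. It was at 86 to 119.1 TPM in intact and 5.5 to 9.6 TPM in cultured Price libraries. In Gereau it was at 89 to 102.7 and 16.8 to 37.8 TPM. The list therefore does not show that pericytes rose.

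Transcripts of blood and neighbouring tissue fell in Price. Of 7 erythroid genes, 6 fell and 1 rose in Price (adjusted p = 0.00082) and 5 fell in Gereau (median −5.08, adjusted p = 0.00502). Hbb-bs, a β-globin (chromosome 7, minus strand, 103826534 to 103828096), was at 1124 ± 416 TPM in Price intact ganglia and 91.4 ± 16.6 TPM in Gereau intact ganglia, and its log2 fold changes in culture were −9.98 and −6.28. Of 20 skeletal muscle, adipose, cartilage and bone genes, 17 fell and 2 rose in Price (median −3.75, adjusted p = 0.000157), and 4 fell in Gereau with no shift of the list (adjusted p = 0.125). Of 8 genes of spinal cord glia, 6 fell and 1 rose in Price (median −1.94, adjusted p = 0.0227), and 3 fell and 2 rose in Gereau with no shift (adjusted p = 0.242). With an estimated correlation the 3 lists gave adjusted p = 0.116 to 0.223 in Price, and the erythroid list gave adjusted p = 0.232 in Gereau.

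All 38 cell cycle genes rose in both laboratories, with medians of 4.32 in Price (adjusted p = 2.63e-19, and adjusted p = 0.0276 with an estimated correlation) and 4.42 in Gereau (adjusted p = 2.29e-21, and adjusted p = 0.0177 with an estimated correlation). Mki67, a marker of dividing cells, rose from 1.47 ± 0.48 to 59.2 ± 6.80 TPM in Price and from 0.47 ± 0.16 to 64.4 ± 16.2 TPM in Gereau. Of 26 fibroblast genes, 14 rose and 7 fell in Price (median 1.59, adjusted p = 0.00824, and adjusted p = 0.399 with an estimated correlation). In Gereau, 19 rose and 1 fell (1.94, adjusted p = 7.65e-06, and adjusted p = 0.2 with an estimated correlation). Col1a1, a chain of type I collagen, rose from 230.1 ± 42.4 to 1601 ± 156 TPM in Price and from 46.6 ± 8.46 to 918 ± 298 TPM in Gereau. Postn, the matrix protein periostin, had log2 fold changes of 7.11 and 6.31. Of 29 matrix proteases and their inhibitors, 19 rose and 1 fell in Price (median 2.09, adjusted p = 9.66e-07, and adjusted p = 0.0626 with an estimated correlation). In Gereau, 22 rose and none fell (2.38, adjusted p = 2.05e-08, and adjusted p = 0.0251 with an estimated correlation).

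Of 40 cytokine and chemokine genes, 28 rose and 5 fell in Price (median 2.23, adjusted p = 8.85e-08, and adjusted p = 0.0276 with an estimated correlation). In Gereau, 27 rose and 3 fell (2.52, adjusted p = 2.06e-08, and adjusted p = 0.0177 with an estimated correlation). Ccl2, a monocyte chemoattractant, rose from 5.72 ± 2.53 to 188 ± 44.9 TPM in Price and from 3.80 ± 0.96 to 289 ± 31.0 TPM in Gereau, and Il6 had log2 fold changes of 4.63 and 5.08. Of 24 immediate early genes, 13 rose and 1 fell in Price (median 1.20, adjusted p = 0.000548, and adjusted p = 0.143 with an estimated correlation). In Gereau, 12 rose and 1 fell (0.81, adjusted p = 0.0011, and adjusted p = 0.195 with an estimated correlation). Of 31 p53 targets, 22 rose and 2 fell in Price (median 1.93, adjusted p = 1.71e-07, and adjusted p = 0.0365 with an estimated correlation). In Gereau, 19 rose and 2 fell (1.29, adjusted p = 0.000149, and adjusted p = 0.147 with an estimated correlation). Among these the largest changes were of Psrc1, Gtse1 and Ckap2, which also act in cell division (log2 fold changes of 5.42, 5.41 and 4.58 in Price).

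The 23 interferon response genes did not shift in Price (1 higher and 4 lower, adjusted p = 0.143) and shifted in Gereau (9 higher and 2 lower, median 0.69, adjusted p = 0.0498). The Gereau call ended with an estimated correlation (adjusted p = 0.623), without the 2 libraries in doubt (adjusted p = 0.0834), with a pseudocount of 0.1 TPM (0.0548) and after quantile normalization (0.0525), and the lowest value among the alternatives was 0.014, with the replicate block. Isg15, a ubiquitin-like protein induced by interferon, was at 86.7 to 266.9 TPM in Gereau cultures and 14.4 to 87.5 TPM in Gereau intact ganglia, with a log2 fold change of 2.94. Of 24 cholesterol synthesis genes, 22 fell in Price (median −1.44, adjusted p = 3.82e-07, and adjusted p = 0.143 with an estimated correlation) and 4 in Gereau (−0.64, adjusted p = 0.00247, and adjusted p = 0.391 with an estimated correlation). Hmgcs1, which makes a precursor of cholesterol, fell from 719.9 ± 67.2 to 94.6 ± 12.5 TPM in Price and from 448 ± 22.8 to 203 ± 37.4 TPM in Gereau. Of 35 nuclear genes of oxidative phosphorylation, 4 fell in Price (median −0.42, adjusted p = 0.00342, and adjusted p = 0.351 with an estimated correlation) and 1 in Gereau (−0.36, adjusted p = 0.00301, and adjusted p = 0.391 with an estimated correlation).

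The 24 glycolysis and hypoxia genes did not shift (4 higher and 7 lower in Price, adjusted p = 0.359, and 5 higher and 4 lower in Gereau, adjusted p = 0.375). Hk2, hexokinase 2, rose in both (2.44 and 2.43). The 8 sex chromosome genes did not shift either (1 higher in each laboratory, adjusted p = 0.418 and 0.364). The median, mean and test of a list were not all of the same sign for satellite glia in Gereau. The same held for 4 lists in the comparison of culture effects, and for 2 lists in each comparison of laboratories, all of which missed the threshold.

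**Figure D3:**
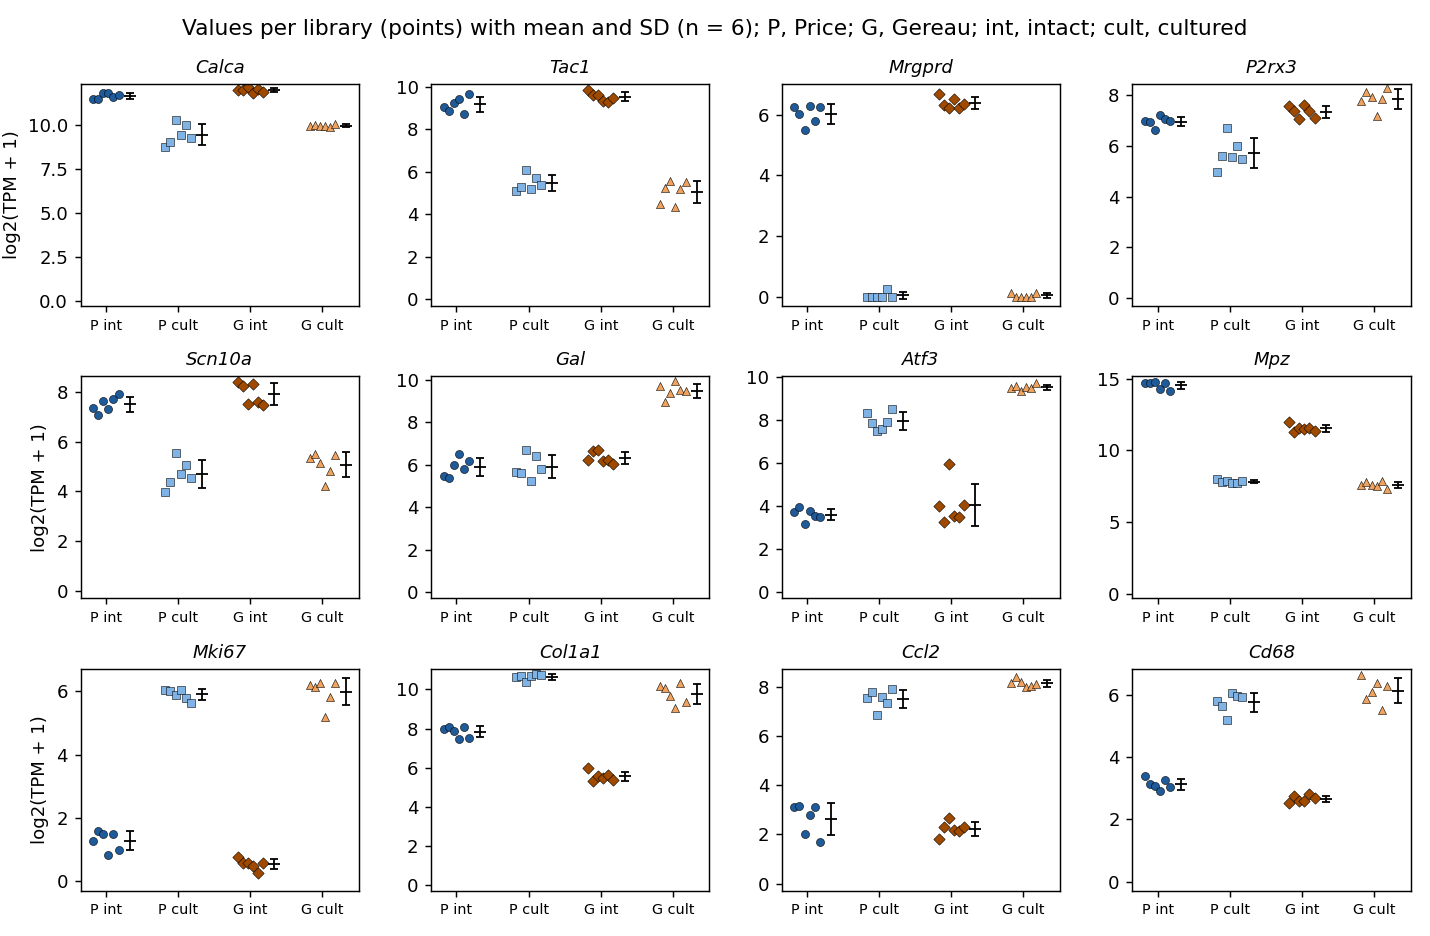
log2(TPM + 1) of 12 genes in each library, 1 point per library, with the mean and SD of each group of 6. Calca, Tac1, Mrgprd, Scn10a and Mpz are lower in the cultures of both laboratories, Mki67, Col1a1, Ccl2, Cd68 and Atf3 are higher, and Gal is higher in Gereau cultures at 736 ± 163 TPM.

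The culture effects of the laboratories, which share no library, overlapped. Of 14459 genes, 1967 were higher in culture in both laboratories (480 expected if calls were independent), 2201 were lower in both (562 expected), and 27 were called in opposite directions. Timp1, Serpine1 and Col1a1 were among those higher in both, and Mpz, Calca, Tac1 and Scn10a among those lower in both. Another 1674 genes were called in Price alone and 944 in Gereau alone, which does not show that their effects differ. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.880. The authors' deposited table marks 2941 entries as differing between cultured and intact ganglia, of which 2926 were tested here and 2371 were called in both laboratories in the same direction.

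The next question was whether target genes fell further or less far than pan-neuronal markers. In each library the mean log2(TPM + 1) of the pan-neuronal list was subtracted from that of each of 10 other neuronal lists, and cultured and intact libraries of a laboratory were compared by a two-sided exact permutation test. Axon injury genes rose against the pan-neuronal markers by 4.21 in Price and 4.26 in Gereau. Voltage-gated calcium channels moved up by 1.12 in Price and 0.45 in Gereau, and TRP, Piezo, ASIC and HCN channels by 1.29 in Price and 0.14 in Gereau. In Price, potassium channels (0.88), ligand-gated channels (0.60) and neuronal G protein-coupled receptors (0.89) also moved up. These lists start lower and have less room to fall: in Price intact ganglia the mean log2(TPM + 1) was 3.91 for potassium channels and 8.85 for pan-neuronal markers. Some members, such as P2rx7, are genes of other cells. Upward moves of channel and receptor lists therefore do not show that neuronal channels fell less than other neuronal genes. In Gereau, marker lists of peptidergic nociceptors (−0.49), non-peptidergic nociceptors and itch neurons (−1.38) and low-threshold and proprioceptive afferents (−0.55) moved down, as did sodium channels (−0.29).

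These 13 of 20 comparisons passed, 11 of them at the smallest p that 6 against 6 libraries allow (exact permutation p = 0.00217, adjusted p = 0.00394), the others being TRP, Piezo, ASIC and HCN channels (adjusted p = 0.0233) and sodium channels (adjusted p = 0.00722) in Gereau. An exact sign-flip test over the 6 mice of a laboratory cannot give a p below 0.0312, and with it none of the 13 passed (smallest adjusted p = 0.0521). With a pseudocount of 0.1 TPM the difference turned negative for ligand-gated channels (−0.27) and G protein-coupled receptors (−0.12) in Price and for TRP, Piezo, ASIC and HCN channels in Gereau (−0.10). The directions of these 3 therefore depend on how genes near 0 TPM are weighted.

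The culture effect was then compared between the laboratories, whose culture protocols differ according to the series description. Relative to their own intact ganglia, Price cultures had lower levels than Gereau cultures of pan-neuronal, injury, myelin, endothelial and interferon response genes, and higher levels of p53 targets. Of these lists, myelin genes and p53 targets alone passed with an estimated correlation (adjusted p = 0.231 for pan-neuronal markers). Gal was at 60.2 ± 18.7 TPM in intact and 62.9 ± 25.7 TPM in cultured Price libraries, against 80.7 ± 16.2 and 736 ± 163 TPM in Gereau, a difference of culture effects of −3.14 ± 0.31 (log2, SE). Stmn2, a microtubule regulator of neurons (ENSMUSG00000027500.10, chromosome 3, plus strand, 8509360 to 8561606), fell from 1868 ± 138 to 338 ± 145 TPM in Price and was at 2475 ± 42.8 and 2016 ± 230 TPM in Gereau (difference −2.27 ± 0.25). Mdm2, a p53 target that limits p53, rose from 29.6 ± 6.24 to 197 ± 16.9 TPM in Price and from 27.4 ± 1.52 to 65.2 ± 22.0 TPM in Gereau (difference 1.56 ± 0.24). limma called 1791 genes, 454 with a more positive and 1337 with a more negative culture effect in Price. After quantile normalization the split was 609 and 1054.

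Among neuronal genes, 14 of 22 pan-neuronal markers had a more negative effect in Price (median −1.29, adjusted p = 7.89e-09), as did 19 of 30 injury genes, against 2 with a more positive one (−1.51, adjusted p = 2.35e-06). Relative to the pan-neuronal markers, however, injury genes rose by 4.21 in Price and 4.26 in Gereau. As a list mean, the difference for injury genes was thus not seen beside that of the pan-neuronal markers. Single members went both ways, Gal having a difference of −3.14 and Csf1 being higher in Price cultures. Csf1 was at 308.3 to 410.4 TPM in Price cultures and 112.9 to 167.8 TPM in Gereau cultures. Injury genes also start lower, at a mean log2(TPM + 1) of 3.70 in Price intact ganglia against 8.85. The list mean therefore does not show that neuronal injury genes differed no more than pan-neuronal markers. Smaller shifts were found for potassium channels (9 more negative and 2 more positive, or 10 and 2 adjusted over the list alone, median −0.35, adjusted p = 0.0361) and ligand-gated channels (6 more negative, median −0.50, adjusted p = 0.0374), and both ended after quantile normalization (adjusted p = 0.386 and 0.194). The adjusted p of these 4 lists was 0.231 to 0.592 with an estimated correlation. P2rx3 (−1.74 ± 0.29) and Scn9a (−1.78 ± 0.50) fell in Price and were not called in Gereau. The lists of peptidergic nociceptors (adjusted p = 0.0558), non-peptidergic nociceptors (0.789), low-threshold afferents (0.1197), sodium channels (0.143), calcium channels (0.0975), TRP and related channels (0.8604) and neuronal G protein-coupled receptors (0.0683) did not shift. The peptidergic list passed with the replicate block (adjusted p = 0.0343) and after quantile normalization (0.0408). Across the alternatives its adjusted p ranged from 0.0343 to 0.592, that of potassium channels from 0.00184 to 0.592 and that of ligand-gated channels from 0.00161 to 0.592.

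Among glia, 16 of 20 myelin genes had a more negative effect in Price (median −1.93, adjusted p = 3.01e-13, and adjusted p = 0.0493 with an estimated correlation), where their intact levels were higher: Mpz had a difference of −2.79 ± 0.17 with cultured levels of 227 ± 16.7 and 196 ± 27.2 TPM. Of 18 satellite glia genes, 7 had a more negative effect in Price (−0.46, adjusted p = 0.0102), among them Glul, glutamine synthetase (−1.90 ± 0.11). Repair Schwann cell genes shifted up (5 more positive and 2 more negative, median 0.38, adjusted p = 0.0380), a call that ended without the 2 libraries in doubt (adjusted p = 0.0546), with a pseudocount of 0.1 TPM (0.058) and after quantile normalization (0.0898), and held with the replicate block (0.0343). Endothelial genes (14 of 20 more negative, median −1.45, adjusted p = 3.72e-07), such as Pecam1 (−2.46 ± 0.34), and fibroblast genes (13 of 26 more negative and 1 more positive, adjusted p = 0.00186), such as Lum (−2.69 ± 0.24), shifted down. The fibroblast list was higher in Price intact ganglia (adjusted p = 1.46e-13, and adjusted p = 0.0649 with an estimated correlation), and between the cultures it missed the threshold (7 higher and 5 lower in Price, median 0.47, adjusted p = 0.148). The satellite, repair, endothelial and fibroblast lists gave adjusted p = 0.107 to 0.552 with an estimated correlation.

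Interferon response genes shifted down (16 of 23 more negative and 1 more positive, median −1.53, adjusted p = 1.43e-06). Bst2, an antiviral membrane protein, was at 71.0 ± 13.3 and 62.2 ± 8.35 TPM in Price and at 55.9 ± 25.6 and 253 ± 82.8 TPM in Gereau (intact and cultured). Of 24 cholesterol synthesis genes, 6 had a more negative effect (7 adjusted over the list alone, median −0.89, adjusted p = 1.01e-08). Lists that were higher in Price intact ganglia shifted down as well: neutrophil and mast cell (10 of 15, median −3.35, adjusted p = 2.35e-06), erythroid (6 of 7, −3.70, adjusted p = 1.43e-06), skeletal muscle, adipose, cartilage and bone (15 of 20 with 3 the other way, −3.36, adjusted p = 6.8e-06) and spinal cord glia (5 of 8, −1.47, adjusted p = 0.0009). With an estimated correlation these 6 lists gave adjusted p = 0.107 to 0.418.

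Of 31 p53 targets, 9 had a more positive effect in Price (median 0.54, adjusted p = 5.17e-08, and adjusted p = 0.0493 with an estimated correlation), among them Ccng1, a cyclin induced by p53 (1.47 ± 0.17). Cytokine genes went both ways (10 more positive and 8 more negative, adjusted p = 0.0975): Lif, a cytokine of the IL-6 family, was at 189 ± 20.1 TPM in Price cultures and 19.7 ± 5.05 TPM in Gereau cultures, and Ccl11, the chemokine eotaxin, at 184 ± 32.4 and 702 ± 122 TPM. Among genes outside the lists, Myzap, a protein of cell junctions (ENSMUSG00000041361.13, chromosome 9, minus strand, 71504347 to 71592360), had a difference of 5.89 ± 0.28, rising to 137 ± 42.9 TPM in Price cultures against 1.42 ± 0.41 TPM in Gereau cultures. Cell cycle genes did not shift (2 of 38 more negative, adjusted p = 0.8604), nor did the lists of macrophages, pericytes, matrix proteases, immediate early genes, oxidative phosphorylation, glycolysis, sex chromosomes, immune and glial receptors, and receptor tyrosine kinases (adjusted p from 0.1197 to 0.916). In all, 16 of 34 lists shifted. Of the 1791 genes, 264 also differed between the intact ganglia of the laboratories and 1234 between their cultures.

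Intact ganglia were compared between the laboratories to give the level from which each culture started. Price intact ganglia had higher levels of myelin, blood and muscle genes than Gereau intact ganglia. Mpz was at 24126 ± 3913 TPM in Price and 3004 ± 546 TPM in Gereau (log2 fold change 3.01), Hbb-bs at 1124 ± 416 and 91.4 ± 16.6 TPM (3.52), and Col1a1 at 230.1 ± 42.4 and 46.6 ± 8.46 TPM (2.27). Acta1, skeletal muscle actin (chromosome 8, minus strand, 123891769 to 123894751), ranged from 30.5 to 986.2 TPM in Price and from 2.1 to 12.6 TPM in Gereau. Its log2 fold change was 4.43, and 3.77 without Price intact replicate 4, where it was highest. limma called 446 genes, 420 higher and 26 lower in Price. The median difference of all genes was −0.06.

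Of 34 lists, 23 shifted, 14 up and 9 down, and 4 still passed with an estimated correlation: myelinating Schwann cell (18 of 20 higher, median 2.21, adjusted p = 4e-04 with an estimated correlation), skeletal muscle, adipose, cartilage and bone (15 of 20 higher, 3.19, adjusted p = 0.00125), erythroid (6 of 7 higher, 3.34, adjusted p = 0.00238) and pericyte (4 of 14 higher, 0.80, adjusted p = 0.000475). Neutrophil and mast cell genes (10 of 15 higher, median 1.57, adjusted p = 1.56e-07), fibroblast genes (10 of 26 higher, 0.74, adjusted p = 1.46e-13), spinal cord glia genes (3 of 8 higher, 0.44, adjusted p = 0.00035), cell cycle genes (4 of 38 higher, 0.23, adjusted p = 9.11e-06) and matrix proteases (4 of 29 higher, 0.46, adjusted p = 6.26e-05) also shifted up, with adjusted p = 0.0649 to 0.298 with an estimated correlation. Neuronal lists shifted down by small amounts, with none of 22 pan-neuronal markers called (median −0.37, adjusted p = 0.000232, and adjusted p = 0.428 with an estimated correlation). Calca was at 3167 ± 349 TPM in Price and 3978 ± 334 TPM in Gereau and was not called. Of 30 injury genes 2 were called lower in Price, and none when adjusted over the list alone. The lists that did not shift in intact ganglia included low-threshold afferents, sodium and calcium channels, macrophages, p53 targets and interferon response genes (adjusted p from 0.1077 to 0.475).

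Cultures of the laboratories were compared directly in the last comparison of groups. Price cultures had lower levels of pan-neuronal, injury, endothelial and interferon response genes than Gereau cultures, and higher levels of p53 targets. Of these lists, p53 targets alone passed with an estimated correlation (adjusted p = 0.305 to 0.379 for the others). Stmn2 was at 338 ± 145 TPM in Price and 2016 ± 230 TPM in Gereau, Gal at 62.9 ± 25.7 and 736 ± 163 TPM, Nts, the neuropeptide neurotensin, at 25.2 ± 13.7 and 329.5 ± 54.8 TPM, and Mdm2 at 197 ± 16.9 and 65.2 ± 22.0 TPM. Serpinb2, an inhibitor of plasminogen activators listed at 0 in all intact libraries, was at 77.5 to 173.5 TPM in Price cultures and 1.9 to 6.2 TPM in Gereau cultures. limma called 1812 genes, 522 higher and 1290 lower in Price.

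Of 34 lists, 20 shifted, 7 up and 13 down, and p53 targets alone passed with an estimated correlation (6 of 31 higher, median 0.70, adjusted p = 0.02 with an estimated correlation). Pan-neuronal markers (18 of 22 lower, −1.73, adjusted p = 1.27e-11), injury genes (20 of 30 lower and 2 higher, −1.82, adjusted p = 2.75e-08), endothelial genes (11 of 20 lower, −1.18, adjusted p = 0.000312), interferon response genes (17 of 23 lower, −1.57, adjusted p = 1.93e-07) and cholesterol synthesis genes (2 of 24 lower, −0.61, adjusted p = 1.38e-06) shifted down, with adjusted p = 0.305 to 0.379 with an estimated correlation. Among channels and receptors, 18 of 51 potassium channel genes were lower and 2 higher (−0.66, adjusted p = 5.28e-05), 11 of 36 ligand-gated channel genes were lower (−0.73, adjusted p = 0.000182), and 18 of 57 neuronal G protein-coupled receptor genes were lower and 1 higher (−0.47, adjusted p = 1.45e-05), with adjusted p = 0.379 to 0.383 with an estimated correlation. P2rx3 and Scn9a were lower in Price cultures (log2 fold changes −2.13 and −1.67), and Piezo1, a mechanically gated channel (ENSMUSG00000014444.17, chromosome 8, minus strand, 122481698 to 122551329), was higher (1.70). Of 20 myelin genes, 4 were higher and 1 lower, and the list did not shift (adjusted p = 0.263). Of the genes that differed between laboratories in intact ganglia and in cultures, 69 were higher in Price in both (15.2 expected if calls were independent), 8 were lower in both (2.32 expected) and 25 differed in opposite directions, and the log2 fold changes correlated across genes at r = 0.227.

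The labels give a sex for each mouse, so libraries labelled female were compared with those labelled male over both laboratories. limma called 0 genes in intact ganglia, 0 in cultures and 0 for the difference between them (374, 712 and 369 genes had an unadjusted p under 0.05). With a pseudocount of 0.1 TPM 4 genes were called in cultures, Comp, Crybb1, Icam2 and Spink2, and 1 for the difference, Spink2, all chosen after their values were seen. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty did not follow the labels in the same direction in both laboratories. Their summed level was 59.7 to 102.5 TPM in the 6 Gereau libraries labelled male and 0 in the 6 labelled female, whereas it was 0 to 5.5 TPM in the 6 Price libraries labelled male and 43.4 to 89.1 TPM in the 6 labelled female. Differences of opposite direction cancel in the average over laboratories, so the 0 calls do not show that the sexes are alike. Ddx3y (ENSMUSG00000069045.11, chromosome Y, minus strand, 1260771 to 1286629) differed between labelled female and labelled male libraries by 3.76 ± 0.22 (log2, SE) in Price intact ganglia and by −3.64 ± 0.22 in Gereau intact ganglia. Fitted within a laboratory, 5 genes were called in Price intact ganglia, 4 in Price cultures, 5 in Gereau intact ganglia and 6 in Gereau cultures. The 4 Y-linked genes were called in every one of these, and the others were Srd5a2, an enzyme of steroid metabolism, in both intact groups (2.26 in Price and −3.43 in Gereau, labelled female minus labelled male), and Cptp and Gm42715 in Gereau cultures, all chosen after their values were seen.

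**Figure D4:**
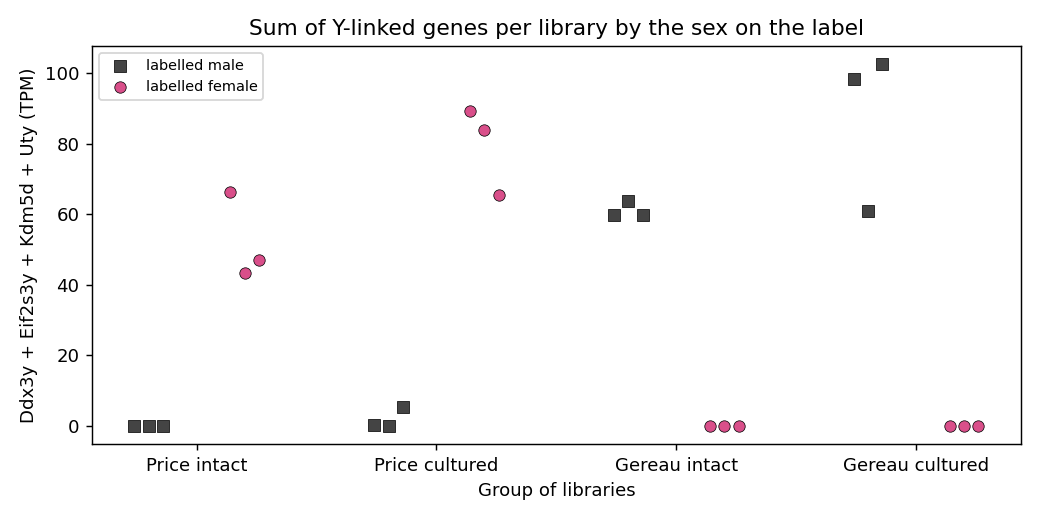
Summed TPM of Ddx3y, Eif2s3y, Kdm5d and Uty in each library, 1 point per library, by group and by the sex given in the labels. Price libraries labelled female lie between 43.4 and 89.1 TPM and those labelled male between 0 and 5.5 TPM, and the Gereau libraries lie the other way round.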

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

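Tests of a lower share of neurons, of other cells multiplied alike, of transcript length, of a mislabelled library and of the 3 explanations for Y-linked genes were chosen after the results were seen. Those of a few abundant genes, of depth and of other splits were not.

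Neuronal genes fell in the cultures of both laboratories, with pan-neuronal medians of −2.90 in Price and −1.51 in Gereau. A lower share of neurons alone, with all neuron types lost equally, requires a like fall of all neuronal genes. However, 19.3% of the neuronal list genes with at least 20 TPM in Price intact ganglia (21 of 109) and 26% in Gereau (32 of 123) fell more than 1 log2 unit beyond the lower quartile of the pan-neuronal markers (−3.35 and −2.13). These include markers of neuron types, such as Mrgprd, Sst and Th. The test therefore cannot tell unequal loss of neuron types from changes within neurons. The medians of 6 non-neuronal lists lay 5.07 apart in Price and 3.15 in Gereau, so these lists did not move alike. Cell numbers were not measured, so the gap does not show that cells multiplied unequally. Within Schwann cell genes, the myelin list had medians of −3.48 in Price and −1.21 in Gereau. The repair and immature list had medians of 1.26 and 1.15. Rescaling without the 10 most abundant genes moved the pan-neuronal median by −0.066 in Price and −0.022 in Gereau. These genes held at most 10.96% of the total of a library, so rescaling could not have moved it by the margin set beforehand. That share itself argues against the 10 most abundant genes taking the total. A smaller share of neuronal RNA may account for part of the pattern. Unequal loss of neuron types, changes within neurons and unequal changes in other cells may account for the rest. This is a biological hypothesis found and tested on the same data, and its parts were not told apart.

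Gereau cultured replicate 4 stood apart from the other 5 libraries of its group, with a median absolute deviation of 0.501 against at most 0.212. Its deviation fell with transcript length (Spearman rho −0.489 across 12675 genes, which are not independent, against at most 0.184 in size for the other 5 when replicate 4 is kept out of their reference, and up to 0.357 when it is part of it), with median deviations of 0.0844, −0.0253, −0.316, −0.521 and −0.797 from the shortest to the longest of 5 equal groups of genes. Removing that trend left 0.354. Length was the median over a gene's annotated protein-coding transcripts, which can differ from the transcript expressed. The remainder therefore cannot tell whether length was the whole cause. Among 2115 genes of at least 100 TPM the deviation was 0.442 against at most 0.188, which argues against lower depth alone. A mislabelled library is argued against by its correlation across genes of 0.955 with its own group and at most 0.922 with another. RNA quality or library preparation that depends on length may be part of the cause, and no biological explanation was tested.

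Y-linked genes lay on opposite sides of the sex labels in the laboratories, Ddx3y differing between laboratories (Price minus Gereau, labelled female minus labelled male) by 7.40 in intact ganglia and 8.13 in cultures. Sex labels correct as given in Price are argued against by these genes. Their sum was 43.4 to 89.1 TPM in the Price libraries labelled female and 0 to 5.5 TPM in those labelled male. Sex labels exchanged in all Price mice would give this pattern and stay open. The X-linked genes Ddx3x, Eif2s3x, Kdm5c and Kdm6a had a labelled female minus male difference of −0.573 in Price and 0.203 in Gereau (two-sided exact permutation p = 0.1, the smallest 3 against 3 mice can give, and p = 0.5). The Gereau value includes cultured replicate 4, labelled female, which stood apart. Its Ddx3x was at 59.3 TPM, against 251.3 and 316.9 TPM in cultured replicates 5 and 6, also labelled female. In intact ganglia the X-linked genes Eif2s3x (−1.36, adjusted p = 0.00387) and Pbdc1 (−1.02, adjusted p = 0.0478), chosen after their values were seen, differed between laboratories in the direction opposite to Ddx3y. Reads shared with X-linked copies are argued against by Ddx3x, whose mean in Price libraries with less than 2 TPM of Ddx3y was 1.41 times that in the others. Libraries exchanged in one preparation are argued against because in 6 of 6 Price mice the intact and cultured library lay on the same side of 10 TPM.

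In all, 232 groups of 6 libraries were tested for a library far from the other 5, and 17 had one, where chance gives about 1 in 20 groups. The number in each case below is the gap to the nearest library as a share of the range. Gereau cultured replicate 4 accounted for 8 of them, being lowest on principal component 3 (0.858) and in the means of neuronal G protein-coupled receptors (0.63), receptor tyrosine kinases (0.784), repair Schwann cell genes (0.703), cell cycle genes (0.718), immediate early genes (0.71) and cholesterol synthesis genes (0.932), and highest in oxidative phosphorylation genes (0.815). Gereau intact replicate 6 was highest in macrophage genes (0.716), interferon response genes (0.679) and Aif1 (0.737), at 31.2 TPM against 1.2 to 9.1 TPM. Price intact replicate 4 had the lowest share of its total in the 10 most abundant genes (0.625), at 8.28% against 9.96% to 10.96%. Price intact replicate 6 was highest in pan-neuronal genes (0.674), Gereau intact replicate 2 highest in muscle, adipose, cartilage and bone genes (0.654), and Price cultured replicate 3 lowest in matrix proteases (0.661). Scn9a was highest in Gereau intact replicate 1 (0.955), at 54.8 TPM against 16.6 to 18.3 TPM, and Atf3 in Gereau intact replicate 3 (0.865), at 61.1 TPM against 8.6 to 15.7 TPM.

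The culture effect differed between the laboratories by a test of the difference for 1791 genes and 16 lists, of which myelin genes and p53 targets alone passed with an estimated correlation. Potassium and ligand-gated channels also missed the threshold after quantile normalization (adjusted p = 0.386 and 0.194). Median differences, Price minus Gereau, were −1.29 for pan-neuronal, −1.51 for injury, −0.35 for potassium channel, −0.50 for ligand-gated channel, −0.46 for satellite glia, −1.93 for myelin, 0.38 for repair Schwann cell, −3.35 for neutrophil, −1.45 for endothelial and −1.002 for fibroblast genes. They were −3.70 for erythroid, −3.36 for muscle, adipose, cartilage and bone, −1.47 for spinal cord glia, 0.54 for p53 target, −1.53 for interferon response and −0.89 for cholesterol synthesis genes. Of the lists of cells from outside the ganglion, the erythroid one shares none of its 7 tested genes with another list and Gereau intact ganglia express 7 at 1 TPM or more, against 1 shared and 9 expressed of 20 in the muscle list and 3 shared and 6 expressed of 8 in the spinal cord list. Among genes always reported, the differences were −1.78 for Scn9a, −1.74 for P2rx3, −1.11 for Atf3, −3.14 for Gal, −2.79 for Mpz, −1.05 for Ccl2, −1.41 for Col1a1 and −3.70 for Hbb-bs. The Atf3 call ended under most alternatives, among them the replicate block (−1.11), no filter (−1.11), no mean-variance trend (−1.11), sex as a covariate (−1.11), array weights (−1.11), a pseudocount of 0.1 TPM (−1.09) and quantile normalization (−1.05). Without single libraries the Atf3 difference ranged from −0.95 (without Gereau intact replicate 2) to −1.49 (without Gereau intact replicate 3).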

How the results depend on the processing

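Alternatives chosen after the data were seen are sex within each laboratory, the leaving out of intermittently listed genes and the leaving out of both libraries in doubt. Of the named genes' values under the alternatives, 21666 kept their direction and side of the threshold, 191 were weaker, 2 stronger and none reversed, and of the list values 658 were the same, 116 weaker and 8 stronger. With adjusted p alone, which drops the fold change by construction, the calls were 11152 and 10713 for culture in Price and Gereau, 4514 for the culture effect by laboratory, and 2765 and 6834 for Price against Gereau in intact ganglia and cultures. A correlation estimated from the data left 13 list calls of 113, and the replicate block left 0 of 13 lists relative to pan-neuronal markers, since 6 mice cannot give a smaller sign-flip p than 0.0312. The replicate block gave 5872 calls for culture in Price, 5142 in Gereau and 1779 for the culture effect by laboratory. It changed no call of a named gene other than Atf3, Chrna7 and Ednrb in the culture effect by laboratory. Price against Gereau holds 1 library per mouse, so a correlation between libraries of a mouse (0.002) took the place of the block. The 446 calls in intact ganglia and 1812 in cultures, equal to the main counts, therefore do not test the pairing. With a pseudocount of 0.1 TPM, sex gave 4 calls in cultures and 1 for its difference by culture. Relative values then became −0.27 for ligand-gated channels and −0.12 for neuronal G protein-coupled receptors in Price, and −0.32 for potassium channels, −0.10 for TRP, Piezo, ASIC and HCN channels and −0.69 for neuronal G protein-coupled receptors in Gereau. The replicate spread became 0.195 in Price intact ganglia, 0.207 in Price cultures and 0.166 in Gereau intact ganglia, more weight falling on genes near 0. Sex gave 5 calls in intact ganglia and 4 in cultures within Price, and 5, 6 and 1 (difference by culture) within Gereau, where Y-linked genes no longer cancel between laboratories. Leaving out single libraries gave 0 to 1 sex calls in intact ganglia, 0 to 5 in cultures (5 without Gereau cultured replicate 6) and 0 to 1 for the difference by culture, and the other counts stayed within 1.5 times their value. Where no construction is named, the cause was not tested. The table has no counts, so how depth limits genes near 0 could not be measured.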

Other observations

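All genes in the next paragraph were chosen after their values were seen. The splits were planned.

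Some drug-target genes rose in lists that fell. Piezo1, a mechanically gated channel, rose from 13.1 ± 2.27 to 135.7 ± 17.6 TPM in Price and from 9.20 ± 1.10 to 41.9 ± 10.1 TPM in Gereau. P2rx7, an ATP-gated channel of immune and glial cells, had log2 fold changes of 1.51 and 2.01, and Kcnn4 and Kcnk5, potassium channels, 2.14 and 2.36 in Price and 1.88 and 2.79 in Gereau. Cckbr, a cholecystokinin receptor induced by nerve injury, had log2 fold changes of 2.70 and 4.16. Adra2a, an adrenergic receptor, fell in Price (−1.05) and rose in Gereau (1.75). Within the macrophage list, Trem2, a receptor for lipids and debris, and Lyz2, a lysozyme, rose in both laboratories (2.95 and 2.70 in Price, 3.17 and 3.03 in Gereau), while H2-Ab1, a chain of MHC class II, fell (−3.28 and −3.90).

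Of the genes in the table, 73 were at most 1 TPM in a library and at least 20 TPM in another of the same group, and 54 of them were tested. Mitochondrial genes were among them, so a listed 0 can be a failed estimate of an abundant transcript.

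Other splits of the same libraries or mice were drawn 100 times for each comparison, the real one included. For called genes, 1 split, the real one, gave as many in all 5 comparisons of culture and laboratory. The counts were 5869 against at most 3983 in another split in Price culture, 5139 against 3403 in Gereau culture, and 1791 against 218 for the culture effect by laboratory. Price against Gereau gave 446 against 187 in intact ganglia and 1812 against 1041 in cultures. Chance was thus excluded for these comparisons other than the culture effect by laboratory. There, whole mice were moved between laboratories, which also mixes the laboratory differences within intact ganglia and within cultures. That split therefore does not isolate the culture effect by laboratory. The highest other splits had 1 library or mouse out of place on each side. Among the splits that part all 6 pairs of libraries of a mouse, 1 of 32 gave as many calls in each laboratory (at most 3983 and 3403 in another), and other splits gave at most 3959 and 3122. For lists passing, Gereau culture met the share of splits fixed beforehand (1 of 100), though by 1 list (27 against 26). All 100 splits passed some lists there, so the count of lists cannot exclude chance. The share was not met for Price culture (17 splits, 27 against 27) or the culture effect by laboratory (8, 16 against 20). Nor was it met for Price against Gereau in intact ganglia (5, 23 against 25) and in cultures (11, 20 against 25). For sex the outcome was fixed in advance, since every split gives at least 0: 100 of 100 splits gave at least the 0 genes called by limma in intact ganglia, in cultures and for the difference by culture (at most 2, 10 and 2 in another split), where 374, 712 and 369 genes had an unadjusted p under 0.05.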
